A study of Homo sapiens with 18 samples.

How the data were processed

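Gene expression was measured in K562 cells, an established human line of chronic myelogenous leukaemia, on 18 two-colour Agilent arrays. Each array set 2 RNA samples against each other, labelled with Cy5 and Cy3. The 3 kinds of array compared TNFalpha-treated with untreated cells, heteronemin-treated with untreated cells, and cells given both agents with TNFalpha-treated cells. Heteronemin, a sesterterpenoid from marine sponges, was given at 6 µM, with DMSO for the controls, at 0 h. TNFalpha, an inflammatory cytokine, was given at 10 ng/mL, with water for the controls, at 2 h. Cells had been thawed 10 days before, and were harvested at 6 h, after 4 h with TNFalpha. From each sample 700 ng of RNA was labelled. The replicates are biological per the series' design text: each comparison has 3, and each of them has 2 arrays with the dyes exchanged, which are technical repeats, so n = 3 per comparison.

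The deposited values are log2 ratios, 1 per feature and array, which the authors made with limma. Its version, the background correction and the normalization are not given in the sources used here. The median over all features lay between −0.0145 and 0.0669 on the 18 arrays, so the ratios had been centred near 0. Whether the arrays were also scaled to each other stays unknown. The ratios were read as treated over control on every array. This direction rests on the array titles and on the large changes, which had the same sign on both arrays of a dye-exchanged pair, so the exchanged arrays had been turned before deposit. A group of unnamed features behaved the other way and changed sign with the dye: 141 were over 1 and 129 under minus 1 on the log2 scale in replicates 2 and 3. They were left out of the gene tests. Intensities and backgrounds were not used here, so the depth behind each ratio is unknown, and the number of arrays limits the precision.

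Of 45220 features, 31425 had a gene entry. The 93 features with several genes and the 13795 without a gene were left out. The remaining 31332 features stood for 18334 genes, of which 7759 had more than 1 feature and were taken as the mean of their features. Of 56 called values of named genes with several features, 3 had 1 feature of the opposite sign: CASP10 and DUSP16 under heteronemin and TUBB4B in cotreated cells. No value was missing. The 2 arrays of each biological replicate were averaged. The correlation across genes between the 2 arrays of a pair was 0.0331, 0.243 and 0.106 in replicates 1 to 3 of TNFalpha against untreated. It was 0.473, 0.484 and 0.315 for heteronemin against untreated, and 0.513, 0.510 and 0.259 for cotreated against TNFalpha-treated cells. Genes are not independent replicates, so these correlations carry no p-value.

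The 9 averaged values per gene were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per comparison and a spread pooled over the comparisons and moderated by empirical Bayes (prior degrees of freedom 2.73, median residual SD 0.116). Beside the 3 measured comparisons, 2 contrasts were tested. The interaction is the heteronemin effect with TNFalpha minus that without it. The indirect comparison of cotreated with untreated cells adds 2 comparisons, since no array made it directly. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Values are given as the mean log2 ratio ± SD over the replicates. For the 2 contrasts the SD is that of the differences or sums within a replicate number.

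The design, the named genes, the gene lists and most alternatives were fixed before the data were examined. The named genes are the 10 highest and 10 lowest called genes of each measured comparison with the same sign on all 6 arrays, and 5 in each direction for the 2 contrasts. Where too few passed, the genes with the smallest p were taken, up to 5 in a direction, as values that did not pass. Up to 4 members of each list with the smallest p were added, and a fixed set of inflammatory, stress and apoptosis genes. The 27 lists cover NF-kB targets, TNF receptor and IKK components, immediate-early genes, pro-apoptotic and anti-apoptotic genes, heat shock genes, proteasome subunits, NRF2 targets, ATF4 targets, ER chaperones, metallothioneins and p53 targets. They also cover G1/S genes, G2/M genes, MYC and ribosome biogenesis genes, erythroid and megakaryocytic genes, cholesterol synthesis, interferon-stimulated genes, glycolysis, histones, tubulins, autophagy genes, ribosomal proteins, lymphoid markers, monocyte and granulocyte markers, and reference genes. Each list was tested against the other genes with camera (preset inter-gene correlation 0.01, two-sided), adjusted over the 108 tests of 27 lists in 3 comparisons and the interaction. Of the 23 lists called, none held with an estimated correlation. A call lost in this setting need not come from correlated genes. For pro-apoptotic genes and p53 targets the estimated correlation was −0.00325 and −0.0396, below the preset value. Their unadjusted camera p under TNFalpha still went from 9.65e-06 to 0.00280 and from 2.86e-05 to 0.00399.

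The replicate numbers were checked for pairing from the data, since the labels do not say whether a number stands for the same cells. The deviations of replicates 1 to 3 from their mean correlated across genes at 0.781, 0.626 and 0.622 between the 2 heteronemin comparisons, with −0.708 to 0.555 between different numbers. These comparisons share no RNA on any array, so number 1 pairs these samples. For numbers 2 and 3 the pairing is less sure, since 0.626 and 0.622 lie near 0.555. Deviations from a mean of 3 are also tied to each other. Fits with the replicate number as a block, 1 effect common to the 3 comparisons, were added. Between TNFalpha against untreated and cotreated against TNFalpha-treated cells the values were −0.326, −0.220 and −0.274, all below the −0.155 to 0.302 between different numbers. A negative sign is what the TNFalpha-treated RNA gives when a number shares it, as numerator of the former and denominator of the latter. TNFalpha and heteronemin against untreated showed no such tie.

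The method was tested on simulated data with 200 changed genes, drawn at random from all genes, of log2 size 0.5, 1 or 2. Each gene had its own spread per comparison. Of 67 genes at 0.5, limma called 52, 57 and 56 in TNFalpha against untreated, heteronemin against untreated and cotreated against TNFalpha-treated cells, and all 66 genes at 2 in each. Among unchanged genes it called 15, 69 and 177, since the pooled spread is too small for the comparisons that vary most. Fitted alone, each comparison recovered 168, 141 and 126 of the 200 changed genes with 5, 3 and 4 false calls. These shares hold for genes of ordinary spread. In the data NFKBIA at 2.96 and BCL3 at 2.48 under TNFalpha were not called. The simulation therefore does not tell how often real responses of such size are found. In the list test 2 of 100 unchanged lists had an unadjusted p under 0.05, but the simulated genes were independent of each other. In the data the estimated correlation was 0.18 for the NF-kB list and 0.80 for histones. The simulation therefore cannot tell how often lists of correlated genes are called without a change.

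The alternatives were: centring or scaling the arrays, each comparison fitted alone, the 18 arrays with a dye term and a random block, a replicate block, a trended and robust prior, arrays of 1 dye orientation alone, other treatments of several features per gene, a size threshold, a limit on the difference within dye pairs, and leaving out each replicate of a comparison. The trended prior followed each gene's mean absolute log2 ratio, since intensities were not used. Genes with large ratios can thus get a larger prior spread, so missing calls with this prior may reflect the setting itself. For the lists, the overlap and the TNFalpha-induced genes, leaving each replicate number out of all 3 comparisons was planned. For the gene counts and named genes it was added after the data were seen, as were array weights and fits of differences and sums within replicate numbers. For comparisons with TNFalpha-treated or untreated cells in common, 100 runs of simulated unchanged groups that share this RNA gave the values beside the observed ones. Figures were drawn with matplotlib 3.10.9 in python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.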

Results

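The arrays compared K562 cells in 4 states: untreated, given TNFalpha, given heteronemin, and given both. Each of 3 comparisons had 3 biological replicates, and 18334 genes were tested. The spread of the genes' log2 ratios (SD over genes) was 0.141, 0.134 and 0.135 in replicates 1 to 3 of TNFalpha against untreated. It was 0.329, 0.195 and 0.164 for heteronemin against untreated, and 0.384, 0.215 and 0.173 for cotreated against TNFalpha-treated cells, so replicate 1 spread most in both heteronemin comparisons.

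The arrays of TNFalpha-treated against untreated cells ask which transcripts the cytokine alters within 4 h. Its receptor signals through NF-kB, a family of transcription factors of inflammation, and the list of NF-kB target genes rose as a group. Of 46 measured members 43 had a positive mean, with a median log2 ratio of 0.38 and a mean of 0.92 (adjusted p = 2.31e-57; adjusted p = 0.0648 with an estimated correlation). Feedback regulators of the pathway were among the members with high ratios: NFKBIA, which encodes the inhibitor that holds NF-kB in the cytosol, was at 2.96 ± 0.46 (SD, n = 3; adjusted p = 0.0749). BCL3, an atypical member of the inhibitor family, was at 2.48 ± 0.72 (adjusted p = 0.0567), and TNFAIP3, which encodes the deubiquitinase A20, at 1.19 ± 0.26 (adjusted p = 0.190).

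Other values were CD83, a surface marker of activated immune cells, at 2.44 ± 0.93, and NINJ1, an adhesion and membrane rupture protein, at 1.34 ± 0.33. KREMEN2, a receptor for Dickkopf proteins, was at 1.17 ± 0.35. The NF-kB subunit RELB was at 1.83 ± 1.15, NFKB1 at 0.40 ± 0.34 and NFKB2 at 0.28 ± 0.18, and TNF itself at 0.28 ± 0.22. The chemokine CXCL8 differed widely between replicates, with 0.0042, 3.59 and 2.95 in replicates 1 to 3, as did the adhesion molecule ICAM1 with 0.027, 2.36 and 1.77. RELB ran the other way, with 2.82, 2.10 and 0.56. Among genes below 0, those with the smallest p had small ratios and did not pass: ZNF696 was at −0.31 ± 0.06 (adjusted p = 0.190), ZNF800 at −0.27 ± 0.12, IL17RA at −0.20 ± 0.05, ORM1 at −0.30 ± 0.08 and R3HCC1L at −0.45 ± 0.28.

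No single gene passed the threshold in limma: 0 of 18334 genes were called, with 315 at an unadjusted p under 0.05 (173 higher, 142 lower) and a smallest adjusted p of 0.0567. Adjusted over the list alone, 25 NF-kB members were higher. With the replicate number as a block 7 genes rose, all in the NF-kB list: BCL3 (adjusted p = 0.00454), NFKBIA (0.00770), IER3, LTB, TNFAIP2 and TNFAIP3 (0.0212 each), and NINJ1 (0.0414). The block fits 1 replicate effect common to the 3 comparisons. Replicate deviations here did not pair with those of heteronemin against untreated (r = −0.210, 0.0306 and −0.0948). They ran opposite to those of cotreated cells (−0.326, −0.220 and −0.274). These 7 calls thus rest on a shared effect that the check did not show for TNFalpha against untreated. Without replicates 1 to 3 in turn in this comparison limma called 17, 0 and 2 genes, all higher. Without replicate 1 in all comparisons, a setting chosen after the data were seen, 59 genes rose and 3 fell, among them 21 NF-kB members. CXCL8 was then at 3.27 (adjusted p = 3.50e-05) and ICAM1 at 2.06 (adjusted p = 0.000769).

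**Figure D1:**
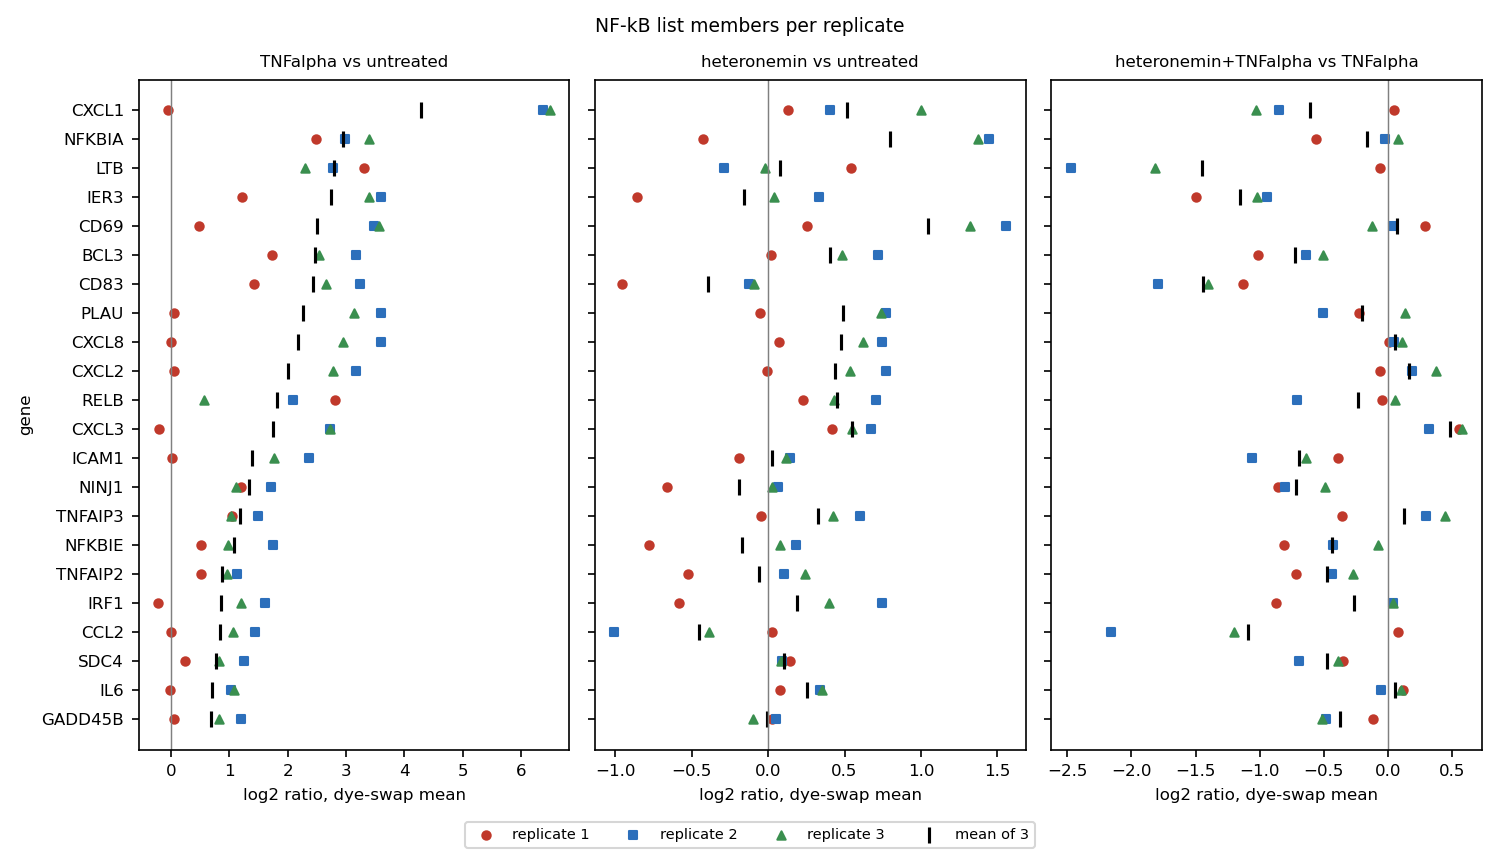
Log2 ratios of the 22 NF-kB list members at 1 or more in the mean of TNFalpha replicates 2 and 3, in the 3 comparisons, with a marker per replicate (n = 3) and a bar at the mean. In replicate 1 of TNFalpha against untreated 10 of these members keep under 10 percent of the ratio in the others, while NFKBIA stands at 2.48.

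Further lists were called under TNFalpha with smaller shifts. The median log2 ratio was 0.070 for immediate-early genes, 0.032 for pro-apoptotic genes and 0.084 for p53 targets. It was −0.034 each for G2/M genes and for MYC and ribosome biogenesis genes. Without replicate 1 these medians were 0.091, 0.022, 0.013, −0.015 and −0.010 in this order. Immediate-early genes rose (adjusted p = 0.000788; adjusted p = 0.638 with an estimated correlation), with JUNB at 0.93 ± 0.62 and the MAPK phosphatase DUSP10 at 0.47 ± 0.24 as the 2 members higher adjusted over the list alone; without replicate 2 the adjusted p was 0.0584. Pro-apoptotic genes rose (adjusted p = 0.000174; adjusted p = 0.144 with an estimated correlation), with the BH3-only gene PMAIP1 at 0.52 ± 0.12 as the 1 member adjusted over the list alone. The p53 target list rose (adjusted p = 0.000343; adjusted p = 0.144 with an estimated correlation), with PLK3 at 0.57 ± 0.50 and GADD45A at 0.34 ± 0.25, and 0 members adjusted over the list alone. G2/M genes fell (adjusted p = 0.0261; adjusted p = 0.923 with an estimated correlation), with the checkpoint kinase BUB1B at −0.15 ± 0.09; without replicates 1 and 2 in turn the adjusted p was 0.220 and 0.0670. MYC and ribosome biogenesis genes fell (adjusted p = 0.0261; adjusted p = 0.923 with an estimated correlation), with nucleolin, NCL, at −0.16 ± 0.13; without replicates 1 and 3 in turn the adjusted p was 0.359 and 0.107. In both of these lists 0 members were called, over all genes or adjusted over the list alone. The ATF4 target list was not called (adjusted p = 0.382), but was higher without replicate 1 (adjusted p = 0.0492).

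Heteronemin-treated against untreated cells show what the compound does without the cytokine. The transcripts of the integrated stress response, in which the factor ATF4 drives amino acid supply and cell death genes, rose together. DDIT3, which encodes the pro-apoptotic factor CHOP, rose by 2.42 ± 0.25 on the log2 scale (SD, n = 3; adjusted p = 0.000155), and ATF3, a stress-induced repressor, by 1.73 ± 0.67 (adjusted p = 0.0105). SESN2, a stress-induced inhibitor of mTORC1, rose by 1.48 ± 0.29, the transcription factor CEBPB by 1.43 ± 0.20 (adjusted p = 0.000721 each), and CHAC1, which degrades glutathione, by 1.40 ± 0.29 (adjusted p = 0.000877). JUN, the AP-1 subunit of the JNK pathway, rose by 2.899 ± 1.06 (adjusted p = 0.0341). Of 35 measured ATF4 targets 19 rose and none fell, 22 adjusted over the list alone, with a median of 0.49 (adjusted p = 9.83e-23; adjusted p = 0.189 with an estimated correlation).

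The other highest genes were HBP1, a transcriptional repressor, at 1.42 ± 0.05, CTH, an enzyme of cysteine synthesis, at 1.40 ± 0.77, TEX19 at 1.39 ± 0.50 and JDP2, an AP-1 repressor, at 1.26 ± 0.51. SLC38A2, an amino acid transporter, rose by 0.86 ± 0.12 (adjusted p = 0.000871). The genes that fell most were PLD6, a mitochondrial surface protein, at −1.71 ± 0.47 (adjusted p = 0.00258), and FJX1 at −1.49 ± 0.12 (adjusted p = 0.000356). RRS1, a ribosome assembly factor, fell to −1.11 ± 0.59, GET1 to −1.07 ± 0.50 and FAM83D to −1.01 ± 0.34. GEMIN6, BEND3, NANOS1, MIR17HG, the host gene of a microRNA cluster, and TMEM177 fell between −0.99 and −0.92.

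Cell death and signalling genes rose singly. BBC3, which encodes the BH3-only protein PUMA, rose by 1.08 ± 0.22 (adjusted p = 0.000850), PMAIP1 by 0.72 ± 0.26 and BMF by 0.59 ± 0.22, but the pro-apoptotic list as a whole, with 4 members up and 1 down of 22, was not called. Among immediate-early genes 5 rose, including KLF6 at 1.22 ± 0.31 and DUSP10 at 1.00 ± 0.06, and 0 fell; the list was not called (adjusted p = 0.248), but was without replicate 1 (adjusted p = 0.00939, with 9 up and 2 down). Of 18 p53 targets 4 rose, with DDB2 at 0.44 ± 0.16 and TP53INP1 at 0.41 ± 0.06, in a list that camera did not call and fry did (adjusted p = 0.00714). The autophagy genes GABARAPL1 and ULK1 rose by 0.72 and 0.50.

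Metallothioneins and the zinc response rose as a list (adjusted p = 0.000343; adjusted p = 0.850 with an estimated correlation). The zinc exporter SLC30A1 was the 1 of 10 members that rose, by 1.08 ± 0.30 (adjusted p = 0.0252), against 3 adjusted over the list alone, and the list's median was 0.64, 1.99 and 0.46 in replicates 1 to 3. MT1F was at 1.26 ± 0.65 (adjusted p = 0.0601, and 0.0270 with the replicate number as a block). MYC and ribosome biogenesis genes fell, with a median of −0.24, and of −0.12 without replicate 1 (adjusted p = 0.000274; adjusted p = 0.814 with an estimated correlation). Of 21 members 1 fell, the rRNA processing factor UTP20 at −0.32 ± 0.05, also adjusted over the list alone, while MYC itself was at −0.47 ± 0.98, with −1.60 in replicate 1 and 0.06 and 0.14 in the others. Cholesterol genes fell (adjusted p = 0.0261; adjusted p = 0.815 with an estimated correlation; adjusted p = 0.141 without replicate 2). Of the 18 members 0 fell, 2 adjusted over the list alone, and 1 rose: SREBF2, a regulator of sterol synthesis, at 0.21 ± 0.02 (adjusted p = 0.0287, and 0.0518 with the block).

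Histone genes rose (adjusted p = 0.00398; adjusted p = 0.923 with an estimated correlation) and so did ribosomal protein genes (adjusted p = 0.000692; adjusted p = 0.923 with an estimated correlation), both with 0 called members, of 17 and 36. The histone median was 0.88 in replicate 1 against 0.10 and 0.06 in the others, and without replicate 1 the adjusted p was 0.377. For ribosomal proteins it was 0.158 without replicate 1 and 0.0526 without replicate 2. The NF-kB list was not called (adjusted p = 0.448, median 0.04), but was higher without replicate 1 (adjusted p = 0.00439): NFKBIA was at −0.42, 1.45 and 1.37 in replicates 1 to 3. Of its 46 members 1 rose, TNFAIP8 at 0.42 ± 0.06.

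In total 419 genes rose and 473 fell under heteronemin (892 called, 3333 at an unadjusted p under 0.05), of which 22 and 5 changed at least 2-fold. These calls rest on the spread pooled over the comparisons: fitted alone, limma called 0 genes, and of simulated unchanged genes 69 were called. With a trended and robust prior it also called 0, but a trend on absolute ratios can work against genes with large changes. Without replicates 1 to 3 in turn in this comparison the count was 378, 163 and 464, and without them in all comparisons, chosen after the data were seen, 2540, 2 and 20.

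**Figure D2:**
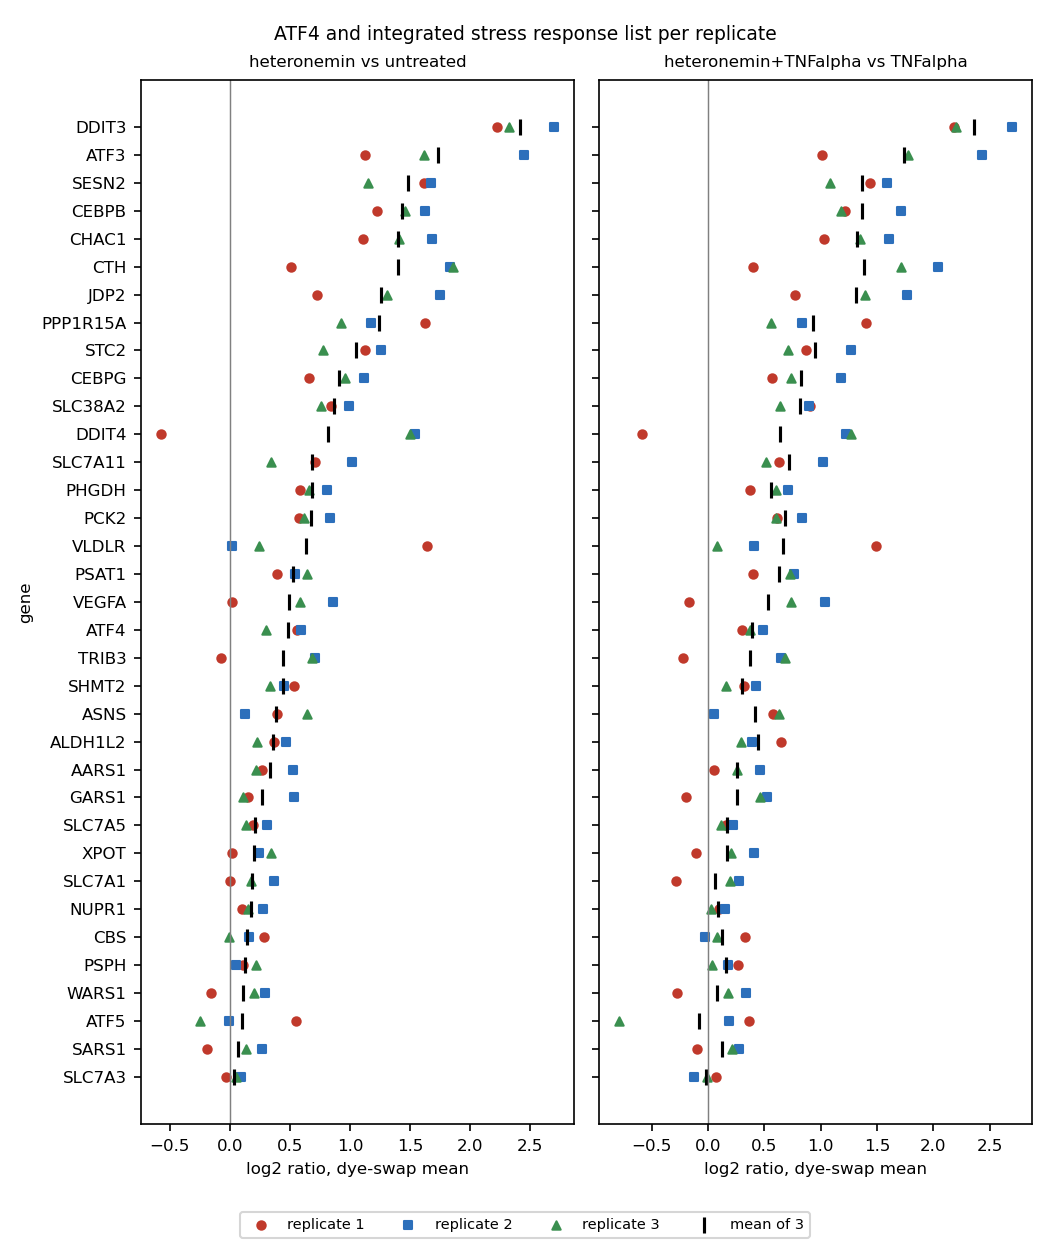
Log2 ratios of the 35 measured ATF4 list members for heteronemin against untreated and cotreated against TNFalpha-treated cells, with a marker per replicate (n = 3) and a bar at the mean. All 35 means are above 0 in the former and 33 in the latter, with DDIT3 at 2.42 and 2.36.

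Cotreated against TNFalpha-treated cells show the compound's effect on cells that also met the cytokine. The stress response rose here too: DDIT3 by 2.36 ± 0.30 (SD, n = 3; adjusted p = 0.000188), ATF3 by 1.74 ± 0.71 (adjusted p = 0.00846), SESN2 by 1.37 ± 0.26, CEBPB by 1.37 ± 0.30 and CHAC1 by 1.33 ± 0.29. JUN rose by 2.64 ± 1.76 (adjusted p = 0.0401), with 4.66 in replicate 1 and 1.84 and 1.42 in the others. Of the 35 ATF4 targets 18 rose and none fell, 22 adjusted over the list alone, with a median of 0.54 (adjusted p = 5.02e-18; adjusted p = 0.258 with an estimated correlation). Several genes with a high TNFalpha ratio fell: CD83 by 1.44 ± 0.33 (adjusted p = 0.0268), KREMEN2 by 0.90 ± 0.25 (adjusted p = 0.00491) and NINJ1 by 0.71 ± 0.20 (adjusted p = 0.0320). TNFalpha-treated RNA is the control here, so part of such a fall may come from shared RNA. Other genes with a positive TNFalpha ratio rose: PMAIP1, at 0.52 under TNFalpha, by 0.69 (adjusted p = 0.0104), and DUSP10, at 0.47, by 0.70 (adjusted p = 0.00548).

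The NF-kB target list fell, with a median of −0.10 and a mean of −0.22 (adjusted p = 0.0197; adjusted p = 0.923 with an estimated correlation), and 16 of 46 means above 0. CD83, NINJ1 and the survival gene BCL2L1, at −0.24 ± 0.10, fell, TNFAIP8 rose by 0.44 ± 0.25, and 42 members did not pass; adjusted over the list alone 5 fell and 2 rose. Others stayed near the TNFalpha level or below without passing: ICAM1 at −0.70 ± 0.34 (adjusted p = 0.306), TNF at −0.22 ± 0.15, RELB at −0.23 ± 0.41, NFKBIA at −0.17 ± 0.34, TNFAIP3 at 0.13 ± 0.43 and CXCL8 at 0.06 ± 0.05. Further members fell more but did not pass: LTB at −1.45 (adjusted p = 0.0646), IER3 at −1.15 and CCL2 at −1.09. Without replicate 2 the list was not called (adjusted p = 0.0778), and without replicate 1 14 members fell and 5 rose, ICAM1 at −0.85 (adjusted p = 0.00559) among the former.

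The other highest genes were HBP1 at 1.45 ± 0.25, TEX19 at 1.43 ± 0.61, CTH at 1.39 ± 0.87 and the metallothionein MT1F at 1.33 ± 0.92 (adjusted p = 0.0403). The genes that fell most were PLD6 at −1.55 ± 0.44 and FJX1 at −1.54 ± 0.21 (adjusted p = 0.000275), then GET1, RRS1, BEND3 and NANOS1 between −1.14 and −1.06, MIR17HG at −0.97 ± 0.09 and DEGS1, an enzyme of ceramide synthesis, at −0.93 ± 0.12. The metallothionein list rose (adjusted p = 4.07e-05; adjusted p = 0.815 with an estimated correlation), with 2 of 10 members up, MT1F and SLC30A1 (1.22 ± 0.68), 9 adjusted over the list alone, and medians of 0.97, 2.62 and 0.33 in replicates 1 to 3. Pro-apoptotic genes were not called as a list: 5 rose, among them BBC3 at 0.89 ± 0.06, and the death receptor gene TNFRSF10A fell by 0.33 ± 0.08. Immediate-early genes were not called (adjusted p = 0.338), but were higher without replicate 1 (adjusted p = 0.0278).

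Lists of growth and structure genes fell. G1/S genes fell, with a median of −0.15, though of 0.031 without replicate 1 (adjusted p = 0.0302; adjusted p = 0.923 with an estimated correlation; adjusted p = 0.659 without replicate 1), with 3 members down, the replication genes FEN1 at −0.62 ± 0.30 and PCNA at −0.32 ± 0.11 and the cyclin CCND3 at −0.28 (adjusted p = 0.0471, and 0.0516 with the replicate block). Adjusted over the list alone 7 fell and 1 rose, and under heteronemin alone the list was not called (adjusted p = 0.0502, and 0.0132 with the block). MYC and ribosome biogenesis genes fell (adjusted p = 0.000528; adjusted p = 0.815 with an estimated correlation), with RRP9 at −0.44 ± 0.31 as the 1 member down and 0 adjusted over the list alone. Cholesterol genes fell (adjusted p = 0.00295; adjusted p = 0.638 with an estimated correlation; adjusted p = 0.109 without replicate 1), with IDI1 at −0.40 ± 0.25 down and SREBF2 at 0.20 up; adjusted over the list alone 6 fell and 1 rose. Tubulins fell (adjusted p = 0.0160; adjusted p = 0.923 with an estimated correlation): TUBB at −0.32 ± 0.10 and TUBB4B at −0.32 ± 0.04 fell, TUBB2B rose by 0.31, and adjusted over the list alone 6 fell and 1 rose. Of 28 G2/M genes 4 rose, CDC25C at 0.61 ± 0.18, TTK at 0.49 ± 0.16, HMMR at 0.47 ± 0.19 and BUB1 at 0.29 ± 0.10, in a list that was not called. Histone genes rose (adjusted p = 0.000752; adjusted p = 0.923 with an estimated correlation) with medians of 1.12, −0.00024 and 0.11 in replicates 1 to 3 and an adjusted p of 0.309 without replicate 1. Ribosomal proteins rose (adjusted p = 0.0302; adjusted p = 0.923 with an estimated correlation), with an adjusted p of 0.511 without replicate 1 and 0.177 without replicate 3; both lists had 0 called members.

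In total 622 genes rose and 578 fell (1200 called, 3883 at an unadjusted p under 0.05), of which 23 and 7 changed at least 2-fold. Fitted alone, or with a trended and robust prior, limma called 0 genes here too, and of simulated unchanged genes 177 were called. Without replicates 1 to 3 in turn in this comparison the count was 1024, 336 and 626, and without them in all comparisons 3397, 2 and 8.

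The overlap of both heteronemin comparisons asks whether the compound acts alike with and without TNFalpha; they share no RNA on any array. Of the genes that rose, 419 and 622, 343 were shared, with 14.2 expected for independent comparisons (odds ratio 286, Fisher's exact test, two-sided). At least replicate number 1 pairs these comparisons and a gene's spread is common to both, so shared deviations add to the overlap. Of those that fell, 473 and 578, 343 were shared, with 14.9 expected (odds ratio 197), and 0 genes were called in opposite directions. Shared genes at least 2-fold changed numbered 16 up, DDIT3, ATF3 and JUN among them, and 4 down. Across all genes the mean log2 ratios correlated at Pearson r = 0.839 and Spearman rho = 0.699, where genes are not independent replicates. Without replicates 1 to 3 in turn the shared genes numbered 1983, 2 and 8.

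**Figure D3:**
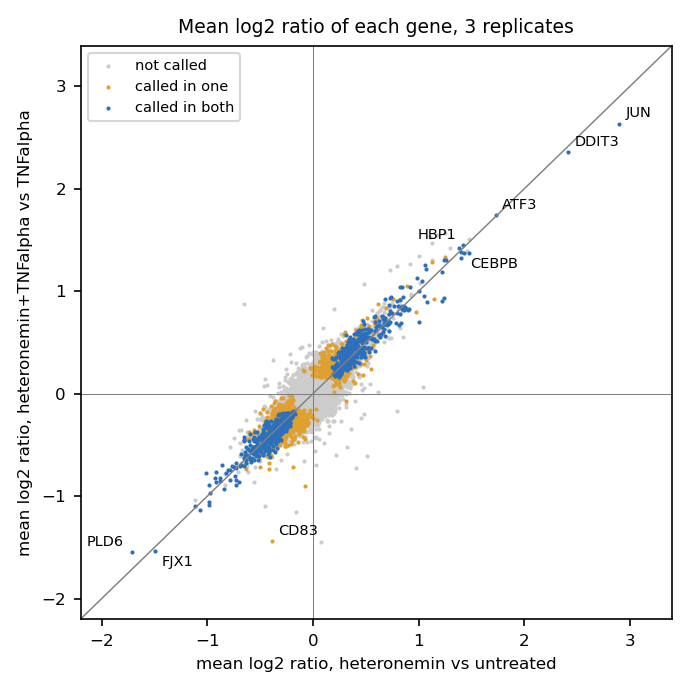
Mean log2 ratio (n = 3) of each gene for heteronemin against untreated (x axis) and for cotreated against TNFalpha-treated cells (y axis), with a line at equal values; blue genes were called in both, orange genes in 1 of them and grey genes in neither. The 686 genes called in both lie near the line, with JUN and DDIT3 at the upper end and PLD6 and FJX1 at the lower end.

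The interaction asks whether heteronemin acts differently once TNFalpha is present. The NF-kB list was lower with the cytokine than without it, with a median of −0.19, a mean of −0.34 and 8 of 46 means above 0 (adjusted p = 3.04e-07; adjusted p = 0.638 with an estimated correlation). Its members with the smallest p were BCL3 at −1.13 ± 0.20 (SD, n = 3), LTB at −1.53 ± 0.82, SDC4 at −0.58 ± 0.17 and CFLAR at −0.18 ± 0.02, and NFKBIA was at −0.96 ± 0.72; none passed alone or adjusted over the list alone. Tubulins were lower too, with 0 of 12 means above 0 and a median of −0.10 (adjusted p = 0.00291; adjusted p = 0.899 with an estimated correlation), for example TUBA1A at −0.21 ± 0.08 and TUBB at −0.19 ± 0.09. The p53 target list was not called (adjusted p = 0.109, and 0.0464 with the replicate block), but was lower without replicate 1 (adjusted p = 0.00615), and G2/M genes, also not called (adjusted p = 0.662), were then higher (adjusted p = 0.0132). With an estimated correlation 0 of the 27 lists were called in the interaction.

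No gene differed singly in limma: 0 genes were called, with 475 at an unadjusted p under 0.05 (248 higher, 227 lower), and each adjusted p was 1.00. The genes with the smallest p among higher values were ABCA11P at 1.54 ± 1.25, WASHC4 at 0.33 ± 0.10, LINC01842 at 0.30 ± 0.08, NPDC1 at 0.28 ± 0.13 and NOSTRIN at 0.25 ± 0.04. Those with the smallest p among lower values were KREMEN2 at −0.82 ± 0.24, LINC00326 at −0.39 ± 0.03, LCE1E at −0.34 ± 0.05, AQP4-AS1 at −0.26 ± 0.10 and CHRDL1 at −0.26 ± 0.13. Of the 1406 genes called in either heteronemin comparison 1396 had the same sign in both, and their median absolute interaction was 0.09. Without replicate 1, CD69 at −1.48 (adjusted p = 0.00941), IER3 at −1.17 and NFKBIA at −1.38 (adjusted p = 0.0471 each) were called, of which CD69 and IER3 were chosen after their values were seen. Heteronemin alone then had CD69 at 1.44, NFKBIA at 1.41 and IER3 at 0.19, against −0.04, 0.03 and −0.98 in TNFalpha-treated cells.

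The indirect comparison adds 2 sets of arrays to give cotreated against untreated cells. NFKBIA rose by 2.79 ± 0.79 (SD, n = 3; adjusted p = 0.0369), BCL3 by 1.76 ± 0.94 (adjusted p = 0.0490), TNFAIP3 by 1.31 ± 0.57 (adjusted p = 0.0450) and DDIT3 by 2.43 ± 0.27 (adjusted p = 0.00282). HBP1 rose by 1.50 ± 0.18 and the zinc finger factor KLF6 by 1.49 ± 0.62. PLD6 fell by 1.63 ± 0.33, FJX1 by 1.48 ± 0.08, NANOS1 by 1.01 ± 0.19, DEGS1 by 0.91 ± 0.24 and GEMIN6 by 0.90 ± 0.11. CXCL8 was at 2.24 ± 1.95 (adjusted p = 0.242), with 0.016, 3.64 and 3.06 in replicates 1 to 3. In total 143 genes rose and 87 fell (230 called, 2284 at an unadjusted p under 0.05), but limma called 0 with a trended and robust prior and 91 from these comparisons fitted alone. The comparisons may share TNFalpha-treated RNA within numbers, which the labels do not say. Fitted on the sums within replicate numbers, as a replicate block, 0 genes were called (2433 at an unadjusted p under 0.05). The adjusted p was then 0.0656 for DDIT3, 0.113 for NFKBIA, 0.149 for TNFAIP3 and 0.181 for BCL3. Without replicates 1 to 3 in turn in all comparisons the count was 1334, 1 and 0; left out of TNFalpha against untreated alone it was 46, 23 and 4, and out of the cotreated comparison alone 213, 32 and 131.

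Whether heteronemin opposes the cytokine was also read on the genes TNFalpha raised. None was called, so the NF-kB list, fixed without these data, stood in, with its median of −0.10 in cotreated against TNFalpha-treated cells. The 50 genes with the highest TNFalpha ratio had a median of −0.25 there. Simulated unchanged groups that share the TNFalpha-treated RNA gave −0.12. Their spread was that of each gene over the replicates, which holds the missing response of replicate 1. All of this spread was given to the RNA and none to the arrays, and every number was taken to share its RNA. The simulated values may therefore be too large in size. The simulated correlations were also stronger than those observed, so −0.12 is only a rough guide. Across genes the ratios of TNFalpha against untreated and of cotreated against TNFalpha-treated cells correlated at r = −0.133 (rho = −0.119). Simulated unchanged groups gave −0.332, with a covariance of −0.00301 against the observed −0.00255. TNFalpha and heteronemin against untreated, which both have untreated cells as the control, correlated at r = 0.0432 (rho = −0.0066) against 0.331 simulated for shared RNA, with a covariance of 0.000774 against 0.00246. Part of the values against TNFalpha-treated cells may come from shared RNA.

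Lists called in none of the 4 tests are given with their smallest adjusted p. TNF receptor and IKK components had 0.338, anti-apoptotic genes 0.192, interferon-stimulated genes 0.109, and megakaryocytic genes 0.248. Heat shock genes had 0.441, with HSPH1 up by 0.31 and DNAJB4 by 0.71 under heteronemin. Proteasome subunits had 0.140, with the assembly factor POMP down at −0.42 and −0.32 in both heteronemin comparisons. NRF2 targets had 0.359, where the cystine transporter SLC7A11 rose by 0.69 and 0.72 and MAFG by 0.66 and 0.73. ER chaperones had 0.468, where DNAJB9 rose by 0.84 and 0.82 and HSPA5, the main chaperone, was at −0.13 under heteronemin. Erythroid genes had 0.850, with GATA1 at 0.10 ± 0.03 under heteronemin, glycolysis genes 0.555, autophagy genes 0.735 and reference genes 0.736. Lymphoid markers had 0.667 and monocyte and granulocyte markers 0.840.

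**Figure D4:**
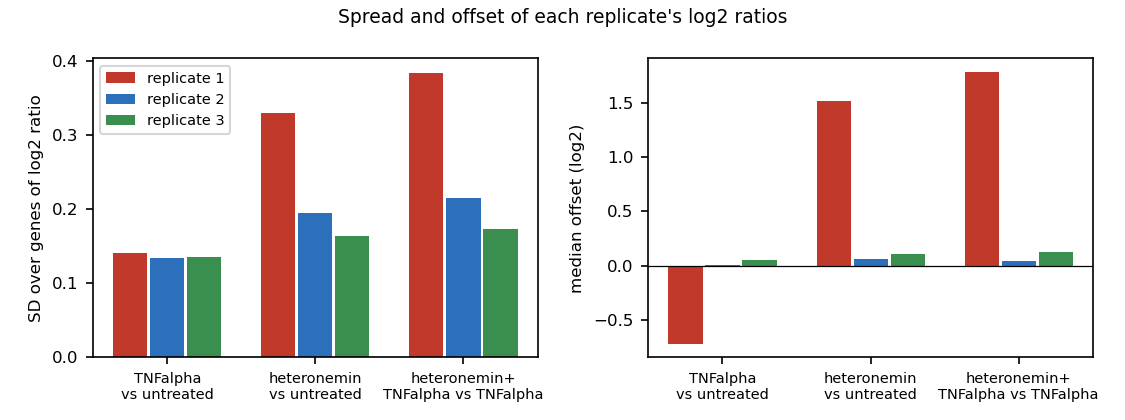
Bars give, for each of 3 biological replicates in the 3 comparisons, the SD of the log2 ratios over genes and the median offset of the unnamed features that follow the dye. Replicate 1 has the largest SD in both heteronemin comparisons (0.329 and 0.384) and offsets of −0.718, 1.52 and 1.79, against 0.00606 to 0.123 in the other replicates.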

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

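The tests of explanations in this part were chosen only after the results they address were seen; the search for far-off arrays, the interaction tests and the splits of replicates were planned. Among 130 groups of 6 arrays, 6 held an array far from the others; chance marks about 1 in 20 groups, and arrays of a dye pair are not independent. In cotreated against TNFalpha-treated cells the median over all features was 0.0669 on array 2, with −0.0145 to 0.0021 on the others. FOS was at −0.69 on array 2 of TNFalpha against untreated, with 0.17 to 0.47 on the others, and XIAP at −0.35 on the same array, with −0.036 to 0.087 on the others. NFKB2 was at 0.27 on array 2 of heteronemin against untreated, with 0.051 to 0.10 on the others. CDKN1A was at 0.79 on array 1 and FJX1 at −2.24 on array 2 of cotreated against TNFalpha-treated cells, where the others lay between −0.26 and 0.11 and between −1.55 and −1.27. All of these arrays belong to replicate 1.

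The effect of heteronemin with TNFalpha differed from that without it for the NF-kB list (adjusted p = 3.04e-07) and for tubulins (adjusted p = 0.00291), neither with an estimated correlation. Features without a gene name that follow the dye should average to near 0 over a dye pair, but their median offset in replicate 1 was −0.718, 1.52 and 1.79 in TNFalpha against untreated, heteronemin against untreated and cotreated against TNFalpha-treated cells.

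Replicate 1 stands apart in both heteronemin comparisons: 176 genes were over 1 higher there than in the mean of the others without TNFalpha, 164 of them also with it, and 48 were over 1 lower in both. Its deviations in the 2 comparisons correlated across genes at 0.781, which argues against noise of single arrays. Genomic DNA in its RNA would raise genes that K562 cells hardly express, but the median deviation of 113 olfactory receptor genes was 0.016. Whether these genes could show such a rise is unknown without intensities. Other genes did rise, and the histone list deviated by a median of 0.84 without TNFalpha and 1.07 with it. This 1 set of genes therefore cannot decide on genomic DNA. A shift shared with the unnamed dye features may account for the higher genes, whose median deviation had the opposite sign in TNFalpha against untreated (−0.40), as the offset had, but not for the 48 lower genes. Nor did each higher gene show it. IER5L and HMX1 were at 4.31 and 2.20 in replicate 1 of heteronemin against untreated, but at −0.075 and 0.011 in that of TNFalpha. FOXC2, NEUROG1 and GPR78 were at −0.50, −0.62 and −0.54 in the latter. These 5 genes were chosen after their values were seen. No biological explanation was tested, and a different state of the cells in that experiment stays open.

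Replicate 1 also lacks part of the TNFalpha response: of 22 NF-kB members at 1 or more in the other replicates, 10 kept under 10 percent, the chemokines CXCL1 and CXCL8 among them, where CXCL1 was chosen after its values were seen. A response weakened alike for all genes is argued against by the 6 members that kept at least 50 percent, such as NFKBIA, RELB and LTB. A failed array beside an intact partner is argued against by the median share of the ratio kept over all 22 members, 0.147 on array 1 and 0.218 on array 2 (upper quartiles 0.516 and 0.645). No biological explanation was tested, so a response that had run for a different time, or other cells, stays open.

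The NF-kB list was lower in cotreated than in TNFalpha-treated cells, but not with an estimated correlation (adjusted p = 0.923) or with fry (adjusted p = 0.433). Replicate 1 alone does not give it, since the list's adjusted p without it was 0.00531, though it was 0.0778 without replicate 2. A fall that needs no TNFalpha cannot be told apart, since the list's mean under heteronemin alone, 0.12, comes from members that go both ways and the difference is lost with an estimated correlation. Without replicate 1 the values go against it at the preset correlation. The list was then higher under heteronemin alone (adjusted p = 0.00439 in camera, with 13 members up and 1 down), and the interaction had an adjusted p of 3.96e-20. Chance in the shared TNFalpha-treated RNA cannot be told apart either: of 59 genes raised in the other replicates 36 were below 0 in replicate 1 (exact two-sided binomial p = 0.118), but that replicate lacks much of the response (median 0.11 against 0.82) and genes are not independent. The fall may reflect opposition to the cytokine, shared RNA or an effect of heteronemin by itself.

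The replicates give too few splits for a share under 0.05. Turning the sign of single replicates gave at most 0 genes in the other 3 splits of each comparison, against 0 genes for TNFalpha (as many in 4 of 4 splits), 892 for heteronemin, 1200 for the cotreated and 230 for the indirect comparison (as many in 1 of 4 each). For the interaction, with 0 genes, all 10 splits gave as many and the highest other gave 2; that split parts 1 pair of equal numbers, while the real one parts 3.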

How the results depend on the processing

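Array weights and fits of differences and sums within numbers were chosen only after the data were seen, as was leaving replicate numbers out of all comparisons for the gene counts and named genes; for the lists, the overlap and the TNFalpha-induced genes that was planned, as were the other settings. Over all settings 11988 of the named genes' values kept their side of the threshold, 923 lost the call, 509 gained it and 4 turned. Direction was compared only where a value passed in the full data or in the setting. Values that passed in neither count as kept even where the sign changed. MYC under heteronemin, for example, was at −0.47 in full and at 0.10 without replicate 1. For called lists other than the NF-kB list, whose values are given apart, 122 kept call and direction, 58 lost the call and 0 turned. The cause was not tested. The values turned were SREBF2 under heteronemin (−0.051, Cy5 arrays only), MS4A1 in the cotreated (−0.39) and indirect comparison (−0.57, both Cy5 arrays only), and EGR1 in the cotreated comparison (0.55, adjusted p = 0.0399, without replicate 1, with −0.64 at the lowest, without replicate 2, and −0.17 in full). Centring the arrays or choosing the feature with the largest variance moved no total count by over 1.5 times, though the latter took the genes that fell in the indirect comparison from 87 to 52. Scaling gave 3 genes for TNFalpha, and took the split of the indirect comparison from 143 up and 87 down to 99 and 103, that of cotreated cells from 622 and 578 to 565 and 629, and that of heteronemin from 419 and 473 to 490 and 753.

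For TNFalpha, main count 0, the settings gave 6 (fitted alone), 35 (18 arrays with a dye term), 7 (replicate block), 4 (Cy5 arrays), 4 (Cy3 arrays), 2 (dye pairs within 1) and 42 (array weights). For heteronemin, main count 892, fitting alone and a trended robust prior gave 0 each, and the cause of this was not tested. The 18 arrays gave 1760, Cy3 arrays 553, a ratio of at least 1 gave 27 and array weights 2680. For cotreated cells, main count 1200, these were 0, 0, 2223, 693, 30 and 3445. For the indirect comparison, main count 230, they were 91 alone, 759 on 18 arrays, 0 with the trended robust prior, 1285 on Cy5 arrays, 20 at a ratio of at least 1, 1811 with weights, and 0 for sums within numbers. The interaction, main count 0 with 475 at an unadjusted p under 0.05 in limma, gave 0 in every setting but 1, without replicate 1, and also for differences within numbers. The replicate block moved no other count by over 1.5 times, apart from the sums within numbers, and calls it changed for genes and lists named in the text stand beside them. The 686 shared genes became 20 at a ratio of at least 1 and 2031 with weights.

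Of 23 called lists 0 held with an estimated correlation. Fry, which asks whether a list moves by itself, called 5, of which 4 were among the 23; the other was the p53 target list under heteronemin. For the NF-kB list the adjusted p was 0.0648 for TNFalpha, 0.923 for cotreated cells and 0.638 for the interaction with an estimated correlation, and 0.433 and 0.403 with fry for the latter 2; fry gave 0.0180 for TNFalpha. The list's median of −0.10 became −0.14 for the 59 genes raised in replicates 2 and 3, read in replicate 1; the other 2 such choices held no gene and gave no value. Leaving out replicates gave ranges of 0 to 62 genes for TNFalpha, 2 to 2540 for heteronemin, 2 to 3397 for cotreated cells, 0 to 3 for the interaction, 0 to 1334 for the indirect comparison, 2 to 1983 for shared genes and 21 to 25 lists. For the NF-kB list the adjusted p ranged from 3.44e-62 to 1.34e-30 for TNFalpha, 0.00439 to 0.867 for heteronemin, 0.00531 to 0.0778 for cotreated cells and 3.96e-20 to 0.00480 for the interaction, and its median from −0.12 to −0.057. The numbers of TNFalpha and heteronemin against untreated did not pair (−0.210, 0.0306 and −0.0948). A filter on missing values was not run because none is missing, and without intensities, not used here, the effect of signal over background could not be judged.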

Other observations

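The tests in this part were chosen only after the data were seen. Mitochondrial ribosome genes fell under heteronemin: of 50 genes named MRPL, which encode the large subunit, 8 fell and 1 rose without TNFalpha, with a median of −0.16 (adjusted p = 2.16e-09), and 9 fell in TNFalpha-treated cells, with a median of −0.15 (adjusted p = 4.62e-09; adjusted p = 0.998 with an estimated correlation for both). Of 28 small subunit genes (MRPS) 6 and 5 fell (adjusted p = 0.00128 and 0.000671), with an adjusted p of 0.108 and 0.0460 without replicate 1 and adjusted p = 0.998 with an estimated correlation. RNA polymerase subunits (POLR, 32 genes) fell as well, 7 without and 8 with TNFalpha (adjusted p = 0.000154 and 0.000159; adjusted p = 0.588 with an estimated correlation).

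The 479 zinc finger genes named ZNF were slightly higher, with medians of 0.06 without and 0.07 with TNFalpha, 29 and 48 of them up and 8 and 7 down (adjusted p = 0.0305 and 0.000225; adjusted p = 0.998 with an estimated correlation). Centrosomal genes named CEP rose in TNFalpha-treated cells (6 of 37 up, adjusted p = 0.00221) and in the interaction (adjusted p = 0.00885), and ubiquitin-conjugating enzymes (UBE) were lower by the list test alone, with 1 of 37 up and 1 down (adjusted p = 0.0489; adjusted p = 0.379 without replicate 1). These 11 calls came from 524 tests of 131 families of at least 15 genes that share the start of their symbol, and none held with an estimated correlation, where the adjusted p was 0.588 for CEP and 0.998 for UBE.

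Some stress genes were low in replicate 1 alone and were chosen after their values were seen. HERPUD1, a gene of ER protein quality control, was at 0.22, 2.32 and 1.84 in replicates 1 to 3 of heteronemin against untreated (adjusted p = 0.105, and 0.0321 with the replicate block), DDIT4, an inhibitor of mTORC1, at −0.57, 1.54 and 1.50, and XBP1, a factor of the unfolded protein response, at −0.80, 0.97 and 0.54. The MAPK phosphatase DUSP2 was at −1.64, 0.11 and 0.03.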
